A study of Mus musculus with 48 samples.

How the data were processed

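Gene expression was measured with Affymetrix arrays in 48 samples of whole mouse tissue from the region where oesophagus and stomach meet, 1 array per sample, in 16 groups of 3. The deposited values were log2 signals per probe set, which the authors made by RMA (background correction, quantile normalisation and median polish) in Affymetrix Expression Console, whose version was not given. The 48 array medians lay between 4.03 and 4.27 on the log2 scale, and no 2 arrays were identical. Groups were taken from the sample labels: genotype, diet, animal facility (MRI or Freising) and age. The labels gave no sex of the mice and no pairing, and the sample titles fell into 4 title series that followed the experiment (IL8 line, FXR lines, diet study, Notch lines). Replicate numbers name arrays only.

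Of 34390 probe set entries, 23521 carried 1 gene symbol and were used; the 1814 with several symbols and the 9055 with none were left out. For a symbol with several entries, the one with the highest mean over the 48 arrays was taken, giving 22180 symbols. Genes above the array median in at least 3 arrays were tested, which left 15242. The genome build behind the probe sets was not stated, so no coordinates are given, and gene order was used only to count neighbours of a locus.

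One model with a mean for each of the 16 groups was fitted to all 48 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (32 residual degrees of freedom). From it, 19 comparisons were tested two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison, and genes with adjusted p below 0.05 were called. Errors beside log2 differences are standard errors from this model, which shares 1 estimate of spread among all groups. A further 44 gene lists, 26 of cell type markers and 18 of pathways, were tested with limma's camera at a preset correlation of 0.01; 43 had at least 4 tested members. Every list test was repeated with the correlation estimated from the residuals. Members of a list were also counted after adjustment over the list alone. Lists, comparisons, the filter, the tests and the rule for the genes to name were fixed before the data were examined. The rule took 8 genes from the genotypes and the study question (Il1b, Nr1h4, Notch1, Notch2, Lgr5, Dclk1, Cxcr2, Hes1), the 10 largest increases and decreases among called genes without predicted or clone-named genes, the 5 smallest p-values per direction where fewer than 5 genes passed, and 4 members of each list that passed. From these, examples are given.

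Alternatives fixed beforehand were no filter, a stricter filter, the mean of all entries of a gene, a fit of the compared groups alone, array quality weights, trended robust moderation, cyclic loess, 5 changes of model or samples (a sex-linked score, a title suffix, a skeletal muscle score, age, each facility alone) and leaving out each array. After the data were seen, 2 more were added: leaving out 10 arrays with a hepatocyte or intestinal marker mean above 8, and 2 covariates made of the squamous and skeletal muscle marker means. Arrays were also split in all other ways into groups of the compared sizes, or in 100 drawn ways where there were more. The procedure was tested on simulated data with 15242 genes, in which 80.6% of genes changed by 1 on the log2 scale were called in the mean transgene comparison, 71.6% in a comparison of 3 against 3 arrays and 29.9% in a difference of 2 effects. Of genes changed by 0.5, 34.3%, 7.46% and 2.99% were called, and of 15042 unchanged genes 4, 11 and 7. The simulated noise was independent between genes, with the same spread of a gene in every group. Correlated genes and unusual arrays were not simulated, so these shares do not measure errors that come from them. The number of arrays limits the precision, since each group had 3.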

Results

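The data describe a mouse model of Barrett oesophagus, the replacement of squamous by columnar lining that precedes oesophageal adenocarcinoma. In this model, called pL2, an interleukin-1 beta transgene is active in the squamous lining of the upper gut. The study asked how a high fat diet (HFD), interleukin-8 (IL8), the bile acid receptor FXR and Notch signalling in Lgr5-positive stem cells or Dclk1-positive tuft cells act on progression. The 48 arrays of whole junction tissue formed 16 groups of 3. Wild-type (WT) and pL2 mice on chow came from both facilities, and both genotypes on HFD came from Freising. A line named FXR and its cross with pL2, the IL8 line at 9 and 12 months and 6 pL2 lines with changed Notch genes came from MRI. Within-group correlations of the arrays ranged from 0.827 to 0.988, with a median of 0.964. All differences below are on the log2 scale with standard errors. The p-values rest on a spread within groups estimated over all 16 groups of 3, not the compared groups alone, unless so stated.

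The transgene itself was examined by comparing pL2 with WT mice on chow, as the mean of the differences within each facility (6 pL2 and 6 WT arrays). Il1b rose by 2.11 ± 0.46 (adjusted p = 0.00121), a 4.32-fold difference seen in 6 of 6 pL2 arrays; the probe location is unknown, so transgene and mouse transcripts cannot be separated. S100a8, a subunit of calprotectin carried by neutrophils, rose by 6.11 ± 0.49 (adjusted p = 3.09e-10) in 6 of 6 arrays. Its partner S100a9 (3.47 ± 0.43), the neutrophil surface protein Cd177 (3.73 ± 0.47), the iron-binding defence protein Lcn2 (3.24 ± 0.33) and the neutrophil attractant Cxcl5 (3.24 ± 0.49) were also higher. The receptor for such attractants, Cxcr2, rose by 1.48 ± 0.35 (adjusted p = 0.00233), and the epithelial defensin gene Defb3 rose by 5.20 ± 0.61.

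Limma called 3341 of 15242 genes in this comparison, 1380 higher and 1961 lower; of these, 274 rose and 540 fell at least 2-fold. Of 16 neutrophil markers 8 were higher and none lower (10 adjusted over the list alone; camera adjusted p = 1.63e-07), and of 26 IL-1 and NF-kB cytokine genes 14 were higher (17 adjusted over the list alone; camera adjusted p = 1.45e-08), among them Il1rn, the natural antagonist of the receptor, at 1.60 ± 0.25. These calls were lost at adjusted p = 0.364 and adjusted p = 0.269 with an estimated correlation. The squamous suprabasal list rose (camera adjusted p = 0.00603; adjusted p = 0.773 with an estimated correlation), with 8 of 26 members higher. Those 8 included the stress keratins Krt6a (2.38 ± 0.38) and Krt16 (2.72 ± 0.49) and the cornified envelope gene Sprr1b (3.03 ± 0.48), beside Sprr2f (3.74 ± 0.44), a gene of the same family. The membrane mucin gene Muc13 rose by 3.21 ± 0.51. Cholesterol synthesis genes were higher as a list, with 9 of 14 members called, such as Mvd at 0.81 ± 0.19 (camera adjusted p = 2.18e-06; adjusted p = 0.397 with an estimated correlation).

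Genes of the muscle wall and stroma were lower in pL2 in the mean of the facilities. All 11 smooth muscle markers fell (camera adjusted p = 8.86e-08; adjusted p = 0.397 with an estimated correlation), as did 14 of 15 fibroblast and matrix genes (camera adjusted p = 2.03e-10; adjusted p = 0.269 with an estimated correlation) and 9 of 10 endothelial genes (camera adjusted p = 8.86e-08; adjusted p = 0.269 with an estimated correlation). Examples were the muscle filament gene Des at -2.47 ± 0.65, the tachykinin receptor gene Tacr2 at -2.77 ± 0.63, the fibroblast receptor gene Pdgfra at -1.39 ± 0.23 and the vessel gene Emcn at -1.57 ± 0.25; Des and Tacr2 were lower in 5 of 6 arrays. The pL2_MRI_chow group had the lowest endothelial and fibroblast list means of the 16 groups. Endothelial means of its arrays were 6.28, 5.00 and 5.14, against 6.83, 6.85 and 7.21 in WT mice at MRI. At Freising they were 6.35, 6.43 and 6.10 in pL2 and 6.44, 6.97 and 6.86 in WT mice. Smooth muscle means at Freising were 10.18, 7.21 and 7.77 in pL2 and 9.90, 9.35 and 9.62 in WT mice. The skeletal muscle list was also lower, with 7 of 15 members called (camera adjusted p = 3.64e-05; adjusted p = 0.483 with an estimated correlation); its group means were 4.36 in pL2 and 6.26 in WT mice at MRI, where WT was the highest of the 16 groups, and 3.80 and 3.94 at Freising. Of the enteroendocrine markers 6 of 11 were lower, such as the somatostatin gene Sst at -1.81 ± 0.46 (camera adjusted p = 0.00128; adjusted p = 0.397 with an estimated correlation). Scgb1a1, a secretory cell gene, fell by 3.34 ± 0.89, the largest decrease. With squamous and skeletal muscle marker means as covariates, an alternative chosen after the data were seen, 209 genes were called and Il1b did not pass (1.65, adjusted p = 0.149).

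Within MRI alone limma called 3512 genes and within Freising 250, where Il1b (1.42, adjusted p = 0.264) did not pass. Interferon response genes fell as a list in the mean (median -0.86, camera adjusted p = 9.65e-07; adjusted p = 0.397 with an estimated correlation), but within MRI the median was -0.0769 and Mx1 gave 0.43, while the mean gave -1.14 ± 0.17 for Mx1 and 3 of 6 arrays were lower.

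**Figure D1:**
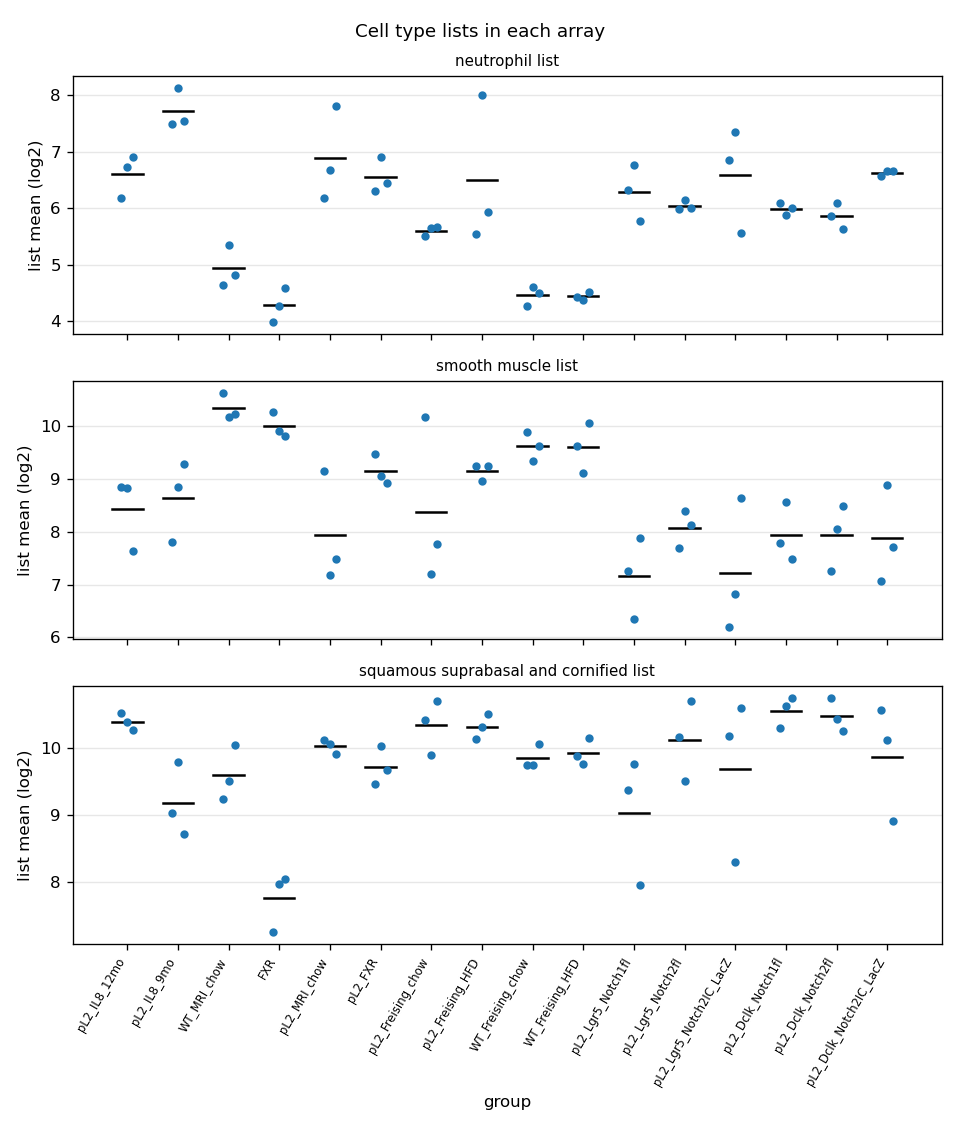
Means of the neutrophil, smooth muscle and squamous suprabasal marker lists (log2) in each of the 48 arrays by group; points are arrays and bars are group means. The FXR group has the lowest group mean of the squamous list, and 1 array of the pL2_Freising_HFD group has a neutrophil mean of 8.01 against 5.54 and 5.94 in the other two.

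Whether the transgene acted differently in the facilities was tested as the Freising difference minus the MRI difference. Interferon-induced genes had a lower transgene difference in Freising: Oas2, a sensor of viral RNA, at -4.46 ± 0.84 (adjusted p = 0.00820), Irf7, a master regulator of interferon genes, at -3.74 ± 0.70 (adjusted p = 0.00820), and Mx1, an antiviral GTPase, at -3.14 ± 0.34 (adjusted p = 1.38e-06). The WT_Freising_chow group stood apart, with an interferon list mean of 6.59 against 5.18 in WT mice at MRI, 4.92 in pL2 mice at Freising and 5.20 in pL2 mice at MRI. Lyz1, a Paneth cell lysozyme gene, differed by -6.73 ± 1.55. Clock output and repressor genes had a higher difference in Freising, such as Dbp at 3.76 ± 0.78, Bhlhe41 at 2.53 ± 0.48 and Nr1d1 at 2.36 ± 0.61, as did Zbtb16, a glucocorticoid-responsive factor, at 4.48 ± 1.00. Limma called 268 genes, 136 higher and 132 lower. The interferon list had 13 of 22 members lower (camera adjusted p = 1.50e-11; adjusted p = 0.324 with an estimated correlation), and 5 of 14 circadian clock genes were higher and 1 lower (camera adjusted p = 0.000217; adjusted p = 0.324 with an estimated correlation). With a sex-linked covariate 56 genes were called; Xist lay above 8 in all 3 WT and 1 of 3 pL2 arrays from MRI and in none from Freising. The title suffix was in all pL2 and no WT chow titles from Freising, and in all titles of both groups from MRI. A title suffix or a skeletal muscle covariate lowered the count as well. The count was 19 without pL2_MRI_chow replicate 3 and 990 without its replicate 1.

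The effect of HFD in pL2 mice was asked as pL2_Freising_HFD against pL2_Freising_chow. No gene passed: limma called 0 genes, with 872 at an unadjusted p below 0.05. The smallest p-values belonged to Cpxm1, a carboxypeptidase-like gene (1.27 ± 0.25, adjusted p = 0.233), and Ctsk, the collagen-degrading cathepsin K gene (1.38 ± 0.30, adjusted p = 0.368). Il1b differed by 1.86 ± 0.65 (adjusted p = 0.689) and did not pass. As a list, macrophage genes were higher, with a median of 0.88 (camera adjusted p = 8.31e-14; adjusted p = 0.0620 with an estimated correlation). No macrophage gene passed over all genes, and 11 of 12 passed adjusted over the list alone, such as the complement gene C1qb at 1.19 ± 0.33. The neutrophil list had a median of 0.88 (camera adjusted p = 1.10e-05; adjusted p = 0.601 with an estimated correlation) and the IL-1 and NF-kB cytokine list 0.59 (camera adjusted p = 9.82e-08; adjusted p = 0.539 with an estimated correlation). The neutrophil mean was 8.01 in pL2_Freising_HFD replicate 2 and 5.54 and 5.94 in the other 2 arrays.

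In WT mice, HFD was compared with chow in the same facility, and 11 of the 25 genes that fell were on the interferon response list. Mx1 fell by 2.78 ± 0.24 (adjusted p = 3.67e-09), a 6.85-fold difference in 3 of 3 arrays. The RNA helicase gene Ddx60 (-3.12 ± 0.53), Slfn4 (-3.01 ± 0.46), Usp18, which removes ISG15 from proteins (-2.64 ± 0.50), Oas3 (-2.54 ± 0.49), Ifit1 (-2.49 ± 0.51), Irf7 (-2.29 ± 0.50) and Zbp1 (-2.12 ± 0.46) fell as well. So did Reg3g, an epithelial antibacterial lectin gene (-2.71 ± 0.59, adjusted p = 0.0330). Limma called 25 genes, all lower, with 660 at an unadjusted p below 0.05. Of 22 interferon response genes 11 fell (14 adjusted over the list alone), and the list held at adjusted p = 0.00129 with an estimated correlation (camera adjusted p = 2.86e-36, median -1.84). The MHC class I list fell with it (median -0.52, camera adjusted p = 1.12e-09; adjusted p = 0.142 with an estimated correlation). Interferon list means were 6.33 to 6.96 in the WT_Freising_chow arrays and 4.46 to 5.65 in the other 45 arrays. The count was 5 without WT_Freising_chow replicate 2 or WT_Freising_HFD replicate 2 and 7 without WT_Freising_HFD replicate 1.

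**Figure D2:**
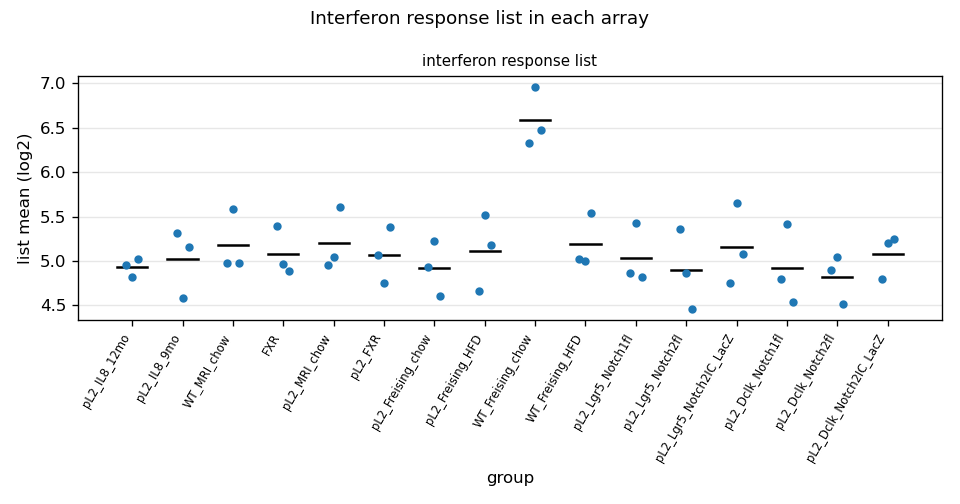
Mean of the interferon response list (log2) in each of the 48 arrays by group; points are arrays and bars are group means. The 3 WT_Freising_chow arrays lie between 6.33 and 6.96, above the other 45 arrays.

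Whether HFD acted differently with the transgene was tested as the difference of the 2 diet effects. Mx1 (2.22 ± 0.34, adjusted p = 0.00147) and Slfn4 (3.55 ± 0.65, adjusted p = 0.0187) had a higher diet difference in pL2 than in WT mice. With the predicted gene Gm20234, named because the count was small and after its value was seen, these were the 3 genes limma called, out of 885 at an unadjusted p below 0.05. The interferon list differed in the same direction (median 1.68, camera adjusted p = 6.99e-24; adjusted p = 0.0180 with an estimated correlation), with 1 of 22 members called over all genes and 14 adjusted over the list alone. This list difference rests on WT mice on chow, whose arrays had means of 6.33 to 6.96 against 4.46 to 5.65 in the other 45 arrays. Macrophage genes had a median difference of 1.15 (camera adjusted p = 1.04e-09; adjusted p = 0.149 with an estimated correlation). The fit of the compared groups alone called 0 genes, and a stricter filter 1.

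IL8 overexpression was asked as pL2_IL8_12mo against pL2_MRI_chow at the same age; the 2 groups lay in different title series, which cannot be separated from genotype. Vessel genes were higher in the IL8 line. Emcn, an endothelial sialomucin gene (2.33 ± 0.36, adjusted p = 0.000404), Podxl (2.17 ± 0.30, adjusted p = 0.000134), the endothelial cadherin gene Cdh5 (2.04 ± 0.30, adjusted p = 0.000335), the TGF-beta co-receptor gene Eng (1.99 ± 0.29) and the pericyte gene Rgs5 (2.05 ± 0.47) rose, each in 3 of 3 arrays. Lower genes included Upk3b (-1.97 ± 0.45) and Msln (-1.42 ± 0.38), both made by mesothelium, the Wnt ligand gene Wnt11 (-1.28 ± 0.33) and Pdx1, a factor of the distal stomach, duodenum and pancreas (-1.20 ± 0.29). Msln and Pdx1 were also called lower in a Notch line, Dclk Notch2fl, against the same reference. Cxcr2, which encodes a receptor for IL8, differed by 0.06 ± 0.49 (adjusted p = 0.972).

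In that comparison limma called 278 genes, 209 higher and 69 lower. Of 10 endothelial genes 9 rose, and the list held at adjusted p = 0.0173 with an estimated correlation (camera adjusted p = 2.54e-17). Fibroblast and matrix genes were higher with 3 of 15 called, such as Col3a1 at 1.02 ± 0.26 (camera adjusted p = 4.49e-08; adjusted p = 0.407 with an estimated correlation). The reference group, pL2_MRI_chow, had endothelial list means of 6.28, 5.00 and 5.14, and the endothelial list was also called higher, at the preset correlation, in each other comparison that had this group as its sole reference. The count was 23 without pL2_MRI_chow replicate 2, 619 without its replicate 1, 30 without the arrays high in liver or intestinal transcripts, and 0 in the fit of the compared groups alone.

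Age within the IL8 line was examined as 12 against 9 months. Xist lay above 8 in 1 of 3 arrays at 12 months and in 3 of 3 at 9 months, so sex-linked transcripts differed along with age. No gene passed: limma called 0 genes, with 1184 at an unadjusted p below 0.05. The squamous suprabasal list was higher at 12 months (median 1.14, camera adjusted p = 5.10e-13; adjusted p = 0.346 with an estimated correlation), with the filaggrin gene Flg at 3.89 ± 1.14 (adjusted p = 0.315) and the mucosal keratin gene Krt13 at 1.47 ± 0.36 (adjusted p = 0.272). The neutrophil list was lower (median -1.12, camera adjusted p = 6.55e-08; adjusted p = 0.346 with an estimated correlation), with the granule genes Mmp8 at -2.61 ± 0.69 (adjusted p = 0.274) and Ngp at -2.10 ± 0.54 (adjusted p = 0.272). The hepatocyte list was higher (median 2.56, camera adjusted p = 6.07e-06; adjusted p = 0.455 with an estimated correlation), and its mean was 8.64 in pL2_IL8_12mo replicate 1.

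The line named FXR was compared with WT mice of the same facility; its label does not say whether the receptor was lost. Nr1h4, which encodes FXR, differed by 0.41 ± 0.37 (adjusted p = 0.648); since the probe location is unknown, this checks nothing about the allele. Squamous genes were lower in the FXR line. Krt16, a keratin of activated squamous epithelium, fell by 4.56 ± 0.70 (adjusted p = 0.000195), a 23.7-fold difference. Krt17 (-3.21 ± 0.47), Krt6a (-3.03 ± 0.54), the envelope gene Sprr2d (-3.04 ± 0.39, adjusted p = 3.33e-05), the desmosome gene Dsg3 (-2.72 ± 0.37) and Trp63, the factor that specifies squamous basal cells (-1.97 ± 0.37), fell too, each in 3 of 3 arrays. Atp2a1, the calcium pump gene of fast skeletal muscle, fell by 3.17 ± 0.71. Higher genes included Glp1r, the incretin receptor gene (2.87 ± 0.75), the endothelin gene Edn1 (1.46 ± 0.29) and the clock gene Npas2 (1.50 ± 0.41). The clock genes Dbp, Ciart and Bhlhe41 were also called, but in the opposite direction to Npas2, lower in the FXR line. Circadian clock list means were 6.43, 6.63 and 6.52 in FXR arrays and 7.34, 6.93 and 7.45 in WT arrays. The tuft cell gene Dclk1 fell by 1.02 ± 0.22 (adjusted p = 0.0108).

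For the FXR line limma called 323 genes, 114 higher and 209 lower. The squamous suprabasal list (11 of 26 lower, 19 adjusted over the list alone), the squamous basal list (7 of 11, 8 over the list alone) and the skeletal muscle list (9 of 15, 15 over the list alone) fell, and all 3 held at adjusted p = 0.0355 with an estimated correlation. The WT reference had the highest skeletal muscle mean of the 16 groups, 6.26 against 4.37 in the FXR line and 3.94 in pL2_FXR. The tuft list fell with 2 of 12 members called (camera adjusted p = 2.60e-05; adjusted p = 0.0842 with an estimated correlation), and the gastric pit list had a median of 0.47 (camera adjusted p = 0.00886; adjusted p = 0.920 with an estimated correlation). The bile acid list did not pass (median -0.45, camera adjusted p = 0.725). Squamous suprabasal means were 7.25, 7.97 and 8.05 in FXR arrays and 9.23, 9.51 and 10.04 in WT arrays. The count was 73 without FXR replicate 2, 45 with a skeletal muscle covariate and 192 in the fit of the compared groups alone; with squamous and skeletal muscle covariates the gastric pit median was -0.38.

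In pL2 mice the same question was asked as pL2_FXR against pL2_MRI_chow. Nr1h4 differed by -0.47 ± 0.37 (adjusted p = 0.895). Matrix and vessel genes rose: the collagen genes Col1a1 (1.65 ± 0.33, adjusted p = 0.0268) and Col3a1 (1.23 ± 0.26), the collagen crosslinking enzyme gene Lox (1.53 ± 0.29), the endothelial receptor gene Tie1 (1.41 ± 0.27), Cdh5 (1.46 ± 0.30) and the endothelial factor gene Sox18 (1.52 ± 0.28), each in 3 of 3 arrays. Limma called 13 genes, all higher, with 1115 at an unadjusted p below 0.05. The endothelial list (adjusted p = 0.0136 with an estimated correlation; 2 of 10 members called and 9 over the list alone) and the fibroblast and matrix list (adjusted p = 0.0402 with an estimated correlation; 2 of 15 called and 11 over the list alone) rose. The reference, pL2_MRI_chow, had the lowest means of the 16 groups in both lists (5.47 and 6.63, against 6.53 and 7.57 in pL2_FXR). Smooth muscle (median 1.29, camera adjusted p = 2.10e-07; adjusted p = 0.442 with an estimated correlation) and macrophage lists (median 0.80, camera adjusted p = 3.63e-08; adjusted p = 0.194 with an estimated correlation) were higher too. The count was 0 without replicate 2 or 3 of either group, 223 without pL2_MRI_chow replicate 1, and 0 in the fit of the compared groups alone, with a sex-linked covariate, or without the arrays high in liver or intestinal transcripts. Xist lay above 8 in 3 of 3 pL2_FXR arrays and in 1 of 3 pL2_MRI_chow arrays, so sex-linked transcripts differed along with genotype.

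The difference between the 2 FXR effects was tested directly. Krt16 (4.63 ± 0.98), Krt17 (3.03 ± 0.67), Dsg3 (2.69 ± 0.52), Col1a1 (2.20 ± 0.47) and the hyaluronan receptor gene Cd44 (1.65 ± 0.30) had a higher FXR difference in pL2 than in WT mice, each at adjusted p = 0.0478. Amigo3 (-1.64 ± 0.36) and Tcta (-1.45 ± 0.30) had a lower one at the same adjusted p. Limma called 21 genes, 14 higher and 7 lower. The squamous suprabasal list differed with 3 of 26 members called (camera adjusted p = 8.23e-10; adjusted p = 0.295 with an estimated correlation). The count was 0 without any 1 of 6 arrays (WT_MRI_chow replicate 3, FXR replicate 1, and replicates 2 and 3 of pL2_MRI_chow and pL2_FXR), 252 without pL2_MRI_chow replicate 1, and 0 with no filter, with a sex-linked or skeletal muscle covariate, or in the fit of the compared groups alone. Xist lay above 8 in all arrays of WT_MRI_chow, FXR and pL2_FXR, but in 1 of 3 of pL2_MRI_chow.

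The Notch lines carry pL2 with an inducible driver in Lgr5 or Dclk1 cells and either a floxed Notch1 or Notch2 gene or an activated Notch2 fragment. Their labels read Notch1fl_fl, Notch2fl_fl and Notch2IC_LacZ, shortened here to Notch1fl, Notch2fl and Notch2IC. Each was compared with pL2_MRI_chow, which differs from them in title series, age and tamoxifen, so these cannot be separated from genotype. Sex-linked transcripts were unbalanced as well. Xist lay above 8 in 1 of 3 pL2_MRI_chow arrays, in 3 of 3 in Dclk Notch1fl and Dclk Notch2fl, and in 2 of 3 in each other Notch line. A title suffix, whose meaning the labels do not give, was present in all pL2_MRI_chow titles and in no Notch2IC title. The targeted genes are expressed in many cell types of this tissue. In the Lgr5 lines Notch1 differed by -0.35 ± 0.22 in Notch1fl (adjusted p = 0.480), and Notch2 by -0.11 ± 0.22 in Notch2fl (adjusted p = 0.914) and 0.25 ± 0.22 in Notch2IC (adjusted p = 0.699). In the Dclk lines Notch1 differed by 0.44 ± 0.22 in Notch1fl (adjusted p = 0.499), and Notch2 by 0.13 ± 0.22 in Notch2fl (adjusted p = 0.852) and -0.10 ± 0.22 in Notch2IC (adjusted p = 0.974). None passed, and the probe location is unknown.

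In the Lgr5 Notch2IC line, Hey1, a direct target of Notch, rose by 1.61 ± 0.33 (adjusted p = 0.0317) in 3 of 3 arrays. The list of Notch targets rose with it and held at adjusted p = 0.0231 with an estimated correlation (camera adjusted p = 0.000401), with 1 of 10 members called and 3 adjusted over the list alone; Nrarp gave 1.22 ± 0.37 (adjusted p = 0.167). List means were 5.64, 5.80 and 5.71 in this line and 5.29, 5.08 and 5.19 in the reference, pL2_MRI_chow. Without any Notch change they were 5.48, 5.44 and 5.49 in WT_MRI_chow and 5.70, 5.21 and 5.32 in pL2_Freising_chow. The reference was thus itself low against WT mice at MRI. List means were also 5.63, 5.59 and 5.61 in WT_Freising_HFD and 5.70, 5.56 and 5.34 in pL2_IL8_12mo. In the remaining groups without a Notch change, arrays lay at 5.60 or lower. Alox12e, an epidermal lipoxygenase gene, rose by 2.28 ± 0.41 and the vessel gene Podxl by 1.44 ± 0.30. Shh, the hedgehog ligand gene, fell by 1.91 ± 0.42, Mgll, the monoglyceride lipase gene, by 1.58 ± 0.30, and Gt(ROSA)26Sor, the locus that commonly carries such transgenes, by 1.15 ± 0.25 (adjusted p = 0.0459). Gastric pit genes were lower as a list (median -0.65, camera adjusted p = 2.27e-06; adjusted p = 0.676 with an estimated correlation). Limma called 21 genes, 9 higher and 12 lower. Without pL2_MRI_chow replicate 2 the count was 0 and Hey1 did not pass (1.43, adjusted p = 0.317), and with an age covariate the count was 0 (Hey1 1.26, adjusted p = 0.313). Hey1 also did not pass with a sex-linked covariate (adjusted p = 0.0707), a title suffix covariate (adjusted p = 0.247), the compared groups alone (adjusted p = 0.8998), without the arrays high in liver or intestinal transcripts (adjusted p = 0.0587), without pL2_MRI_chow replicate 3 (adjusted p = 0.0728) or without pL2_Lgr5_Notch2IC_LacZ replicate 1 (adjusted p = 0.119). Gt(ROSA)26Sor did not pass in any of the settings in which Hey1 did not. It was also lost with no filter (adjusted p = 0.0543), without pL2_MRI_chow replicate 1 (adjusted p = 0.0509) and without pL2_Lgr5_Notch2IC_LacZ replicate 3 (adjusted p = 0.0817). Without pL2_Lgr5_Notch2IC_LacZ replicate 2 the count was 487.

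In the Dclk Notch2IC line Gt(ROSA)26Sor fell by 1.40 ± 0.25 (adjusted p = 0.0155) in 3 of 3 arrays. The ribosomal protein gene Rpl3 (2.07 ± 0.30, adjusted p = 0.000729) and Trmt112, a methyltransferase activator gene (1.00 ± 0.16, adjusted p = 0.00208), rose. These were the 3 genes limma called, out of 1016 at an unadjusted p below 0.05. Hey1 differed by 1.18 ± 0.33 (adjusted p = 0.370), and the Notch target list was higher (median 0.34, camera adjusted p = 0.0186; adjusted p = 0.274 with an estimated correlation). Cell cycle genes were higher as a list (median 0.41, camera adjusted p = 7.27e-07; adjusted p = 0.610 with an estimated correlation). The count was 1 without pL2_MRI_chow replicate 2 and 44 without its replicate 1. Gt(ROSA)26Sor did not pass in the fit of the compared groups alone (adjusted p = 0.654) or with a title suffix covariate (adjusted p = 0.127). It also did not pass without pL2_MRI_chow replicate 2 (adjusted p = 0.361), or without pL2_Dclk_Notch2IC_LacZ replicate 1 (adjusted p = 0.242) or replicate 2 (adjusted p = 0.227).

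In the Lgr5 Notch2fl line, Tpm3, a tropomyosin gene, rose by 1.62 ± 0.24 (adjusted p = 0.000267) and Tmod4, a thin filament capping gene of skeletal muscle, by 1.55 ± 0.15 (adjusted p = 4.47e-08), while the skeletal muscle list was lower (median -0.48, camera adjusted p = 0.0282; adjusted p = 0.851 with an estimated correlation). The corneal keratin gene Krt12 rose by 1.48 ± 0.27. Lyrm7, a respiratory chain assembly gene, fell by 1.66 ± 0.25 and Mul1, a mitochondrial ubiquitin ligase gene, by 0.82 ± 0.12. Limma called 8 genes, 4 higher and 4 lower, with 1385 at an unadjusted p below 0.05. The count was 56 without pL2_MRI_chow replicate 1 and 1 in the fit of the compared groups alone.

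In the Dclk Notch2fl line, Lce1k rose by 4.08 ± 0.80 (adjusted p = 0.0162), Lce1m by 2.49 ± 0.51 and Sprr4 by 2.25 ± 0.40, while the squamous suprabasal list did not pass (camera adjusted p = 0.143). Also higher were the lysozyme-like gene Lyg1 (3.69 ± 0.64) and Il12rb2, a subunit of the interleukin-12 receptor (2.85 ± 0.57). Pdx1 fell by 1.97 ± 0.29 (adjusted p = 0.000810), as did the urothelial gene Upk1b (-2.24 ± 0.49) and Msln (-1.91 ± 0.38). Pdx1 and Msln were also called lower in the IL8 line, which has the same reference, pL2_MRI_chow. In the Dclk Notch1fl line against that reference, Pdx1 was lower too and among the smallest p-values, without passing. A difference that lies in the reference group cannot be told apart here. Limma called 39 genes, 26 higher and 13 lower. The IL-1 and NF-kB cytokine list was lower (median -0.61, camera adjusted p = 3.45e-06; adjusted p = 0.469 with an estimated correlation), and so was the neutrophil list (median -1.09, camera adjusted p = 2.48e-05; adjusted p = 0.588 with an estimated correlation). Neutrophil means were 5.86, 6.09 and 5.63 in this line and 6.19, 6.68 and 7.81 in the reference. In pL2_Freising_chow they were 5.51, 5.64 and 5.66, so the line was not low against pL2 mice on chow at Freising. The count was 6 without pL2_MRI_chow replicate 2, 240 without its replicate 1, and 1 in the fit of the compared groups alone.

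In the Lgr5 Notch1fl line limma called 22 genes, 12 higher and 10 lower. Cdh5 rose by 1.53 ± 0.30, Angptl8, a lipid regulator made by liver and fat, by 2.26 ± 0.45 and the receptor gene Fgfr4 by 1.43 ± 0.30. Gpr27, an orphan receptor gene, fell by 1.60 ± 0.29, the costimulatory ligand gene Icosl by 0.88 ± 0.16 and the corepressor gene Ctbp2 by 0.66 ± 0.10 (adjusted p = 0.00201). In its replicate 2 the hepatocyte list mean was 11.4, and in replicate 3 the intestinal list mean was 9.46. The count was 1 without pL2_MRI_chow replicate 3, 480 without pL2_Lgr5_Notch1fl replicate 3, and 0 with an age covariate. In the Dclk Notch1fl line no gene passed: limma called 0, with 1589 at an unadjusted p below 0.05. Its smallest p-values belonged to the phosphatase gene Inpp4b (1.05 ± 0.20, adjusted p = 0.0821), Phgr1 (-1.78 ± 0.35, adjusted p = 0.0821) and Pdx1 (-1.43 ± 0.29, adjusted p = 0.0821); 83 genes were called without pL2_MRI_chow replicate 1.

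The Notch2IC and Notch2fl lines were compared within each driver, inside 1 title series; Notch2 itself differed by 0.35 ± 0.22 in Lgr5 lines (adjusted p = 0.770) and by -0.23 ± 0.22 in Dclk lines (adjusted p = 0.976). In Lgr5 lines the lipoxygenase genes Alox15 (3.66 ± 0.69, adjusted p = 0.0132) and Alox12e (2.47 ± 0.41, adjusted p = 0.00260) were higher in Notch2IC than in Notch2fl, and Tpm3 (-1.73 ± 0.24) and Tmod4 (-1.66 ± 0.15, adjusted p = 8.04e-09) were lower. Hey1 differed by 1.24 ± 0.33 (adjusted p = 0.260). In Dclk lines Rpl3 was higher in Notch2IC (1.93 ± 0.30, adjusted p = 0.00305), and Sprr4 (-2.20 ± 0.40), Tpm3 (-1.29 ± 0.24) and Tmod4 (-0.80 ± 0.15, adjusted p = 0.0153) were lower. Limma called 11 genes in Lgr5 lines, 7 higher and 4 lower, with 1084 at an unadjusted p below 0.05. It called 5 in Dclk lines, 2 higher and 3 lower, with 793; the fifth was the clone-named 5830417I10Rik, given because the count was small and after its value was seen. The Notch target list rose in Lgr5 lines (median 0.33, camera adjusted p = 0.0300; adjusted p = 0.381 with an estimated correlation). In Dclk lines the squamous suprabasal list was lower in Notch2IC (median -0.59, camera adjusted p = 0.000121; adjusted p = 0.890 with an estimated correlation). The Lgr5 count was 45 without pL2_Lgr5_Notch2IC_LacZ replicate 3 and 0 in the fit of the compared groups alone, and the Dclk count was 0 without pL2_Dclk_Notch2IC_LacZ replicate 2.

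**Figure D3:**
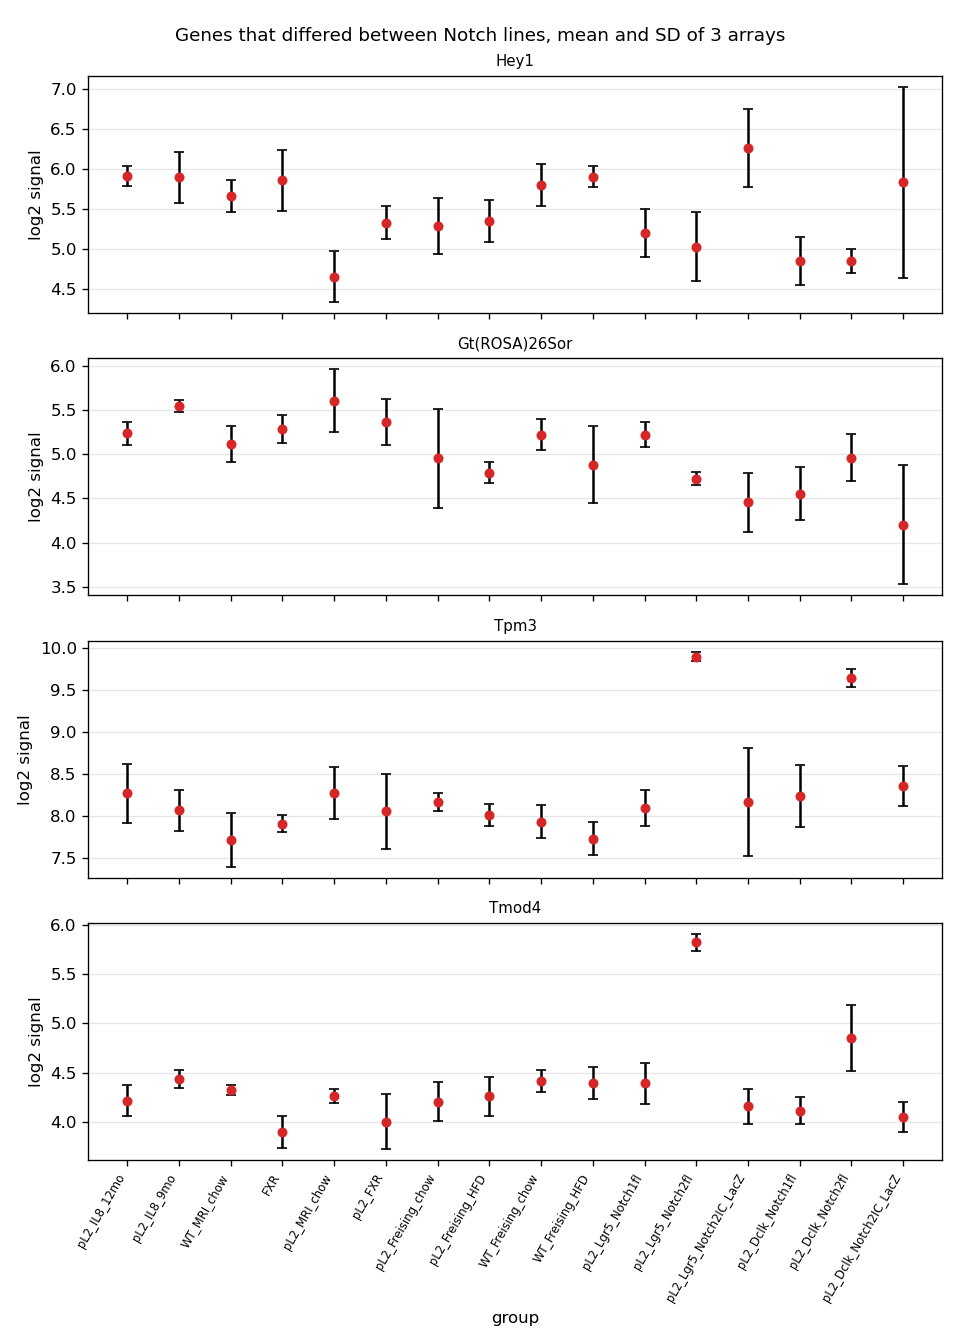
Signals (log2) of Hey1, Gt(ROSA)26Sor, Tpm3 and Tmod4 by group; points are means and bars are standard deviations of 3 arrays. Tpm3 has means of 9.90 and 9.65 in the 2 Notch2fl groups, above every other group.

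The drivers were compared as the mean of the 3 Dclk lines minus that of the 3 Lgr5 lines (9 against 9 arrays). Higher in Dclk lines were genes of the cornified layer such as the protease gene Klk5 (2.93 ± 0.72), Lce1e (2.83 ± 0.69), Flg (2.62 ± 0.66) and Kprp (1.98 ± 0.51), each in 8 of 9 arrays. The hormone genes Sst (1.50 ± 0.37) and Ghrl (1.07 ± 0.27), of the D cells and the ghrelin cells, were also higher. Fcgbp, a goblet cell mucus gene (-1.74 ± 0.45), the glutamate transporter gene Slc1a1 (-1.42 ± 0.29) and Onecut2 (-1.06 ± 0.26) were lower. Lgr5 differed by 0.89 ± 0.27 (adjusted p = 0.0989) and Dclk1 by 0.01 ± 0.13 (adjusted p = 0.981). Limma called 144 genes, 119 higher and 25 lower. The squamous suprabasal list was higher (1 of 26 called, 15 over the list alone; camera adjusted p = 0.000133; adjusted p = 0.687 with an estimated correlation). The enteroendocrine list was higher too (2 of 11 called; camera adjusted p = 0.000159; adjusted p = 0.389 with an estimated correlation), and the intestinal enterocyte list lower (median -0.73, camera adjusted p = 8.64e-10; adjusted p = 0.389 with an estimated correlation). The Dclk mice were 10 to 13 months old and the Lgr5 mice 9 to 11, and with an age covariate the count was 0. Ages at tamoxifen were 5 to 6 months in Dclk lines and 3 to 5 in Lgr5 lines. In the fit of the compared groups alone the count was also 0. It was 51 without the arrays high in liver or intestinal transcripts, 28 without pL2_Lgr5_Notch2fl replicate 2 and 430 without pL2_Dclk_Notch2IC_LacZ replicate 3.

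**Figure D4:**
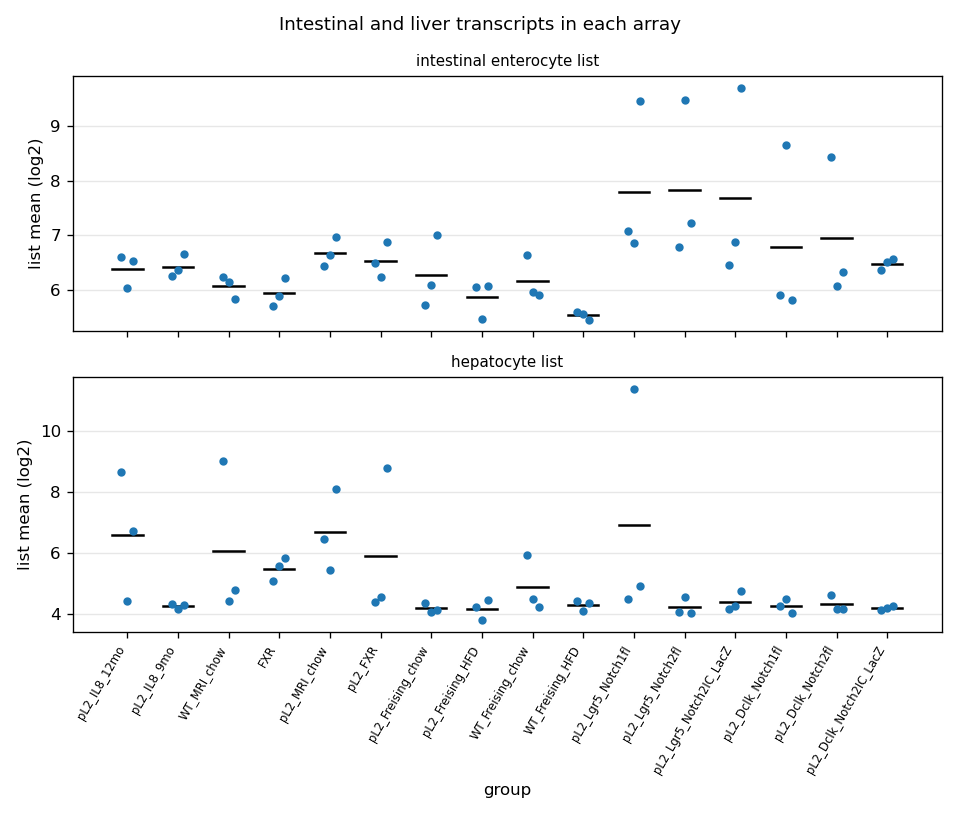
Means of the intestinal enterocyte and hepatocyte marker lists (log2) in each of the 48 arrays by group; points are arrays and bars are group means. Intestinal means exceed 8 in 5 arrays, all from Notch lines, and hepatocyte means exceed 8 in 5 others.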

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

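The tests weighed in the 3 paragraphs on Notch2, interferon and squamous genes were all chosen after those results were seen. The counts of 100 splits of the samples were planned, with 5 or more taken to mean that chance is not excluded. That reading was dropped for the 3 differences of effects after their counts were seen, and the 82 even splits were chosen then. For Dclk against Lgr5 driver, 3 of 100 splits gave as many genes, and chance was left open after the counts were seen. Differences are on the log2 scale.

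The effect of the transgene differed between the facilities for 268 genes by the test of that difference. Among them Zbtb16 gave 4.48, Dbp 3.76, Aspn 2.63, Bhlhe41 2.53, Rasl11b 2.50, Qpct 2.50, Casq1 2.43, Nr1d1 2.36, Neb 2.25 and Itga8 2.19. On the lower side Lyz1 gave -6.73, Oas2 -4.46, Apol9b -4.32, Ifit1bl1 -4.27, Slfn4 -3.96, Irf7 -3.74, Oas1g -3.73, Ddx60 -3.38, Reg3g -3.35 and Oasl2 -3.26. The WT_Freising_chow group stood apart in the interferon list mean (6.59, against 5.18, 4.92 and 5.20 in the other 3 groups). Of 100 splits 7 gave as many genes, which meets the planned rule for chance, and the highest other called 1230, which points to a structure of the samples. Splits exchange arrays between the facilities, and uneven ones carry the facility effect into the count: of the other splits, 6 of 65 uneven and 0 of 34 even ones gave as many. Of all 82 even splits only 1, the real one, did, with 213 in the highest other, so whether chance is excluded is left open. Without pL2_MRI_chow replicate 3 the count was 19, and without its replicate 1 it was 990.

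The effect of HFD differed between pL2 and WT mice for 3 genes, among them Slfn4 at 3.55 and Mx1 at 2.22, and for the interferon list at a median of 1.68. The WT_Freising_chow arrays had interferon list means of 6.33 to 6.96 and the other 45 arrays 4.46 to 5.65, so the list difference rests on that group. Of 100 splits 14 gave as many genes, which meets the planned rule for chance, and the highest other called 805, which points to a structure of the samples. Uneven splits carry the transgene effect here: 13 of 56 uneven and 0 of 43 even ones gave as many, and of all 82 even splits only the real one did (1 in the highest other), so chance is left open.

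The effect of FXR differed between pL2 and WT mice for 21 genes. Higher in pL2 were Krt16 at 4.63, Krt17 at 3.03, Dsg3 at 2.69, Col1a1 at 2.20, Slc28a3 at 2.08, Car12 at 2.04, Cd44 at 1.65, Col15a1 at 1.45, Lamb1 at 1.44 and Sprr1a at 1.35. Lower were Amigo3 at -1.64, Tcta at -1.45, Dnase1l1 at -1.26, Paxx at -1.19, Preb at -1.004 and Dolpp1 at -0.93. Of 100 splits 16 gave as many genes, which meets the planned rule for chance, and the highest other called 2786, which points to a structure of the samples. Here too uneven splits carry the transgene effect: 15 of 60 uneven and 0 of 39 even ones gave as many, and of all 82 even splits only the real one did (3 in the highest other), so chance is left open. The count was 0 without WT_MRI_chow replicate 3 and 252 without pL2_MRI_chow replicate 1.

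Tpm3 and Tmod4 were higher in both Notch2fl lines than in the Notch2IC lines of the same driver, and neither gene is a known Notch2 target on the lists used. A candidate explanation is sequence linked to the floxed Notch2 allele: among the 401 tested genes nearest Notch2 lay 2 of 11 called genes in Lgr5 lines (0.290 expected, Fisher's exact p = 0.0325) and 3 of 5 in Dclk lines (0.132 expected, p = 0.000174), but most of these were Tpm3 and Tmod4 themselves, and the third, Sprr4, belongs to a cluster of squamous genes in the same neighbourhood. More striated muscle in the Notch2fl tissue is argued against in both drivers: WT mice at MRI had a skeletal muscle mean of 6.26, against 3.83 and 4.06 in the Lgr5 and Dclk Notch2fl lines, yet lay below them in Tpm3 (-2.18 ± 0.24 and -1.93 ± 0.24) and Tmod4 (-1.49 ± 0.15 and -0.53 ± 0.15). The skeletal muscle medians, 0.37 and -0.36, both lay above the bound of -0.4 first written; a requirement of 2 spreads (0.42 each), added after they were seen, had left the Dclk lines open until the test on WT mice was added. An effect of Notch2 itself, the biological explanation in the design, was not tested apart from these and stays open.

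The interferon list was low in WT mice on HFD against chow. One array did not make the pattern, since the median was -1.62 or lower whichever array was left out, and fewer immune cells are argued against by T and NK cell and macrophage medians of -0.0105 and -0.12. The WT chow group at Freising may have been high, rather than the HFD group low: the HFD group lay 0.00872 above WT mice at MRI and the Freising chow group 1.41 above them. WT mice at MRI differ in facility and in Xist, so that comparison does not remove those differences. The pL2_Freising_chow arrays share facility and diet with the WT chow group and have no Xist above 8. Their list means were 4.93, 5.22 and 4.61 without HFD, but they differ in the transgene. The WT chow arrays, at 6.33 to 6.96, were the ones apart, since the other 45 arrays, HFD arrays among them, lay between 4.46 and 5.65. A lowering by HFD, the biological explanation in the design, stays open.

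Squamous and skeletal muscle lists were low in the FXR line against WT. Less oesophagus in the dissected tissue is a candidate explanation for the squamous part, since the lowest of the 4 gastric list medians was 0.37, above 0. The muscle part lies in the reference: the WT mice at MRI had the highest muscle mean of the 16 groups, 6.26, while the FXR line was not low, at 4.37 against 3.94 in pL2_FXR and in WT_Freising_chow. The FXR effects with and without the transgene differed for Krt16 (4.63 ± 0.98), Krt17 (3.03 ± 0.67) and Dsg3 (2.69 ± 0.52), each at adjusted p = 0.0478, while for the squamous suprabasal list as a set (median -0.26 in pL2 mice) the test of the difference gave adjusted p = 0.295 with an estimated correlation and leaves an alike effect open. An effect of FXR on squamous cells themselves stays open, untested, since any difference in dissection could not be separated from genotype in these 3 arrays.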

How the results depend on the processing

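The alternatives were fixed before the data were examined, except leaving out 10 arrays high in liver or intestinal transcripts and the pair of squamous and skeletal muscle covariates, which were chosen after the results were seen. No paired analysis was possible because the labels pair no mice and replicate numbers only name arrays. Trended robust moderation left all 19 counts within 1.5 times, cyclic loess 16, the mean of all entries of a gene 17, a stricter filter 17, no filter 15 and a sex-linked covariate 15, while array quality weights left 1. The fit of the compared groups alone, which estimates the spread from as few as 6 arrays, left 5 counts within 1.5 times and 116 of the 318 calls of named genes. Of 246 list calls, 9 held with an estimated correlation. The mean transgene effect kept its count within 1.5 times in every leave-one-out fit (2407 to 3390). Most counts from 3 against 3 arrays depended on single arrays, and pL2_MRI_chow, the reference of 8 comparisons, set the lowest or the highest count in each of them. Where 1 array of a group was left out, the remaining arrays were assumed to vary like those of the other groups. The 4.03 to 4.27 range of array medians limits what can be read for genes near background. The cause of the changes below was not tested, except that a covariate made of a list's own genes removes that list's difference by construction.

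Without a filter on dim genes, limma called 173 genes for the facility difference, 0 for FXR by transgene, 60 for Lgr5 Notch1fl against pL2 and 93 for Dclk against Lgr5 driver. With a stricter filter, limma called 1 gene for HFD by transgene and 14 for Lgr5 Notch1fl against pL2. With the mean of all entries of a gene, limma called 2 genes for Dclk Notch1fl against pL2 and 3 for Dclk Notch2IC against Notch2fl. With a fit of the compared groups alone, limma called 19 genes for the facility difference, 0 for HFD by transgene, 0 for IL8 in pL2, 192 for FXR in WT, 0 for FXR in pL2, 0 for FXR by transgene, 0 for Lgr5 Notch1fl against pL2, 1 for Lgr5 Notch2fl against pL2, 0 for Lgr5 Notch2IC against pL2, 1 for Dclk Notch2fl against pL2, 0 for Dclk Notch2IC against pL2, 0 for Lgr5 Notch2IC against Notch2fl, 1 for Dclk Notch2IC against Notch2fl and 0 for Dclk against Lgr5 driver. With array quality weights, limma called 6235 genes for the mean transgene effect, 3559 for the facility difference, 224 for HFD in pL2, 435 for HFD in WT, 545 for HFD by transgene, 4117 for IL8 in pL2, 311 for IL8 line by age, 866 for FXR in WT, 1580 for FXR in pL2, 1563 for FXR by transgene, 1741 for Lgr5 Notch1fl against pL2, 2297 for Lgr5 Notch2fl against pL2, 1110 for Lgr5 Notch2IC against pL2, 3255 for Dclk Notch1fl against pL2, 4627 for Dclk Notch2fl against pL2, 2430 for Dclk Notch2IC against pL2, 20 for Dclk Notch2IC against Notch2fl and 959 for Dclk against Lgr5 driver. After cyclic loess, limma called 412 genes for the facility difference, 58 for FXR by transgene and 57 for Dclk against Lgr5 driver. With a sex-linked covariate, limma called 56 genes for the facility difference, 0 for FXR in pL2, 0 for FXR by transgene and 9 for Lgr5 Notch2IC against pL2. With a title suffix covariate, limma called 79 genes for the facility difference, 1 for FXR by transgene, 38 for Lgr5 Notch1fl against pL2, 3 for Lgr5 Notch2IC against pL2, 3 for Dclk Notch1fl against pL2 and 0 for Dclk Notch2IC against pL2. With a skeletal muscle covariate, limma called 11 genes for the facility difference, 493 for IL8 in pL2, 45 for FXR in WT, 0 for FXR by transgene, 65 for Lgr5 Notch2IC against pL2, 48 for Dclk Notch1fl against pL2, 173 for Dclk Notch2fl against pL2 and 524 for Dclk against Lgr5 driver. With an age covariate, limma called 0 genes for Lgr5 Notch1fl against pL2, 0 for Lgr5 Notch2IC against pL2 and 0 for Dclk against Lgr5 driver. With squamous and skeletal muscle covariates, limma called 209 genes for the mean transgene effect, 28 for the facility difference, 603 for IL8 in pL2, 71 for FXR in WT, 0 for Lgr5 Notch1fl against pL2, 376 for Lgr5 Notch2IC against pL2 and 29 for Dclk against Lgr5 driver. Within Freising, limma called 250 genes for the mean transgene effect. Without the 10 arrays high in liver or intestinal transcripts, limma called 38 genes for the facility difference, 30 for IL8 in pL2, 1 for IL8 line by age, 0 for FXR in pL2, 2 for FXR by transgene, 38 for Lgr5 Notch1fl against pL2, 21 for Lgr5 Notch2fl against pL2, 11 for Lgr5 Notch2IC against pL2, 19 for Dclk Notch1fl against pL2, 10 for Dclk Notch2fl against pL2, 14 for Dclk Notch2IC against pL2, 62 for Lgr5 Notch2IC against Notch2fl, 3 for Dclk Notch2IC against Notch2fl and 51 for Dclk against Lgr5 driver.

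Values here are medians of lists or log2 differences of genes. With array quality weights, the sign turned for gastric pit mucous (0.10 in HFD in pL2), parietal (0.0485 in HFD in pL2) and interferon response (0.0408 in Lgr5 Notch2fl against pL2, -0.12 in Lgr5 Notch2IC against Notch2fl). With a skeletal muscle covariate, the sign turned for skeletal muscle (0.0908 in the mean transgene effect, 0.00637 in FXR in pL2) and gastric pit mucous (-0.19 in FXR in WT). With squamous and skeletal muscle covariates, the sign turned for squamous suprabasal and cornified (-0.17 in the mean transgene effect, -0.0898 in IL8 line by age, 0.32 in FXR in WT, -0.28 in FXR by transgene, 0.0635 in Lgr5 Notch1fl against pL2), skeletal muscle (0.00398 in the mean transgene effect, 0.00811 in FXR in pL2, -0.0853 in FXR by transgene) and gastric pit mucous (-0.38 in FXR in WT, 0.26 in FXR by transgene). Within Freising, the sign turned for Casq1 (0.11 in the mean transgene effect) and Cpb1 (0.000461 in the mean transgene effect). Within MRI, the sign turned for Mx1 (0.43 in the mean transgene effect). Without the 10 arrays high in liver or intestinal transcripts, the sign turned for B and plasma cell (-0.0453 in Lgr5 Notch2fl against pL2) and skeletal muscle (-0.00552 in Lgr5 Notch2IC against Notch2fl). In the next cases only camera's direction, which is relative to the other genes, turned, while the median kept its sign and came nearer 0. With a skeletal muscle covariate, this held for skeletal muscle (0.0907 in the facility difference, -0.045 in FXR in WT, 0.0232 in FXR by transgene, -0.032 in Lgr5 Notch2fl against pL2, -0.00771 in Dclk Notch1fl against pL2). With squamous and skeletal muscle covariates, this held for skeletal muscle (0.10 in the facility difference, -0.000372 in FXR in WT, -0.0374 in Lgr5 Notch2fl against pL2, -0.0201 in Dclk Notch1fl against pL2), lipogenesis (0.12 in IL8 line by age) and squamous suprabasal and cornified (0.0451 in Dclk Notch1fl against pL2, 0.086 in Dclk against Lgr5 driver). Within MRI, this held for interferon response (-0.0769 in the mean transgene effect). Without the 10 arrays high in liver or intestinal transcripts, this held for cell cycle (0.0322 in FXR in pL2). In 17 other cases the median changed sign while camera's direction did not, and camera's call was lost in each of them. Without pL2_FXR replicate 3, the sign turned in FXR in pL2 for cell cycle (-0.0556, range -0.0556 to 0.43). Without pL2_Freising_HFD replicate 2, the sign turned in HFD in pL2 for gastric pit mucous (0.13, range -0.60 to 0.13), parietal (0.18, range -0.70 to 0.18), T and NK cell (-0.00807, range -0.00807 to 0.73) and adipocyte (0.086, range -0.51 to 0.086). Without WT_Freising_HFD replicate 3, the sign turned in HFD in WT for skeletal muscle (-0.15, range -0.15 to 0.92).

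Leaving out each array in turn gave these ranges, with each count that moved by more than 1.5 times. For the facility difference the counts ran from 19 to 990 (57 without WT_MRI_chow replicate 1, 39 without WT_MRI_chow replicate 3, 990 without pL2_MRI_chow replicate 1, 28 without pL2_MRI_chow replicate 2, 19 without pL2_MRI_chow replicate 3, 31 without pL2_Freising_chow replicate 1, 422 without pL2_Freising_chow replicate 2, 149 without WT_Freising_chow replicate 1, 30 without WT_Freising_chow replicate 2, 106 without WT_Freising_chow replicate 3). For HFD in pL2 the counts ran from 0 to 1 (1 without pL2_Freising_chow replicate 1, 1 without pL2_Freising_HFD replicate 3). For HFD in WT the counts ran from 5 to 25 (5 without WT_Freising_chow replicate 2, 16 without WT_Freising_chow replicate 3, 7 without WT_Freising_HFD replicate 1, 5 without WT_Freising_HFD replicate 2). For HFD by transgene the counts ran from 2 to 5 (5 without WT_Freising_chow replicate 1). For IL8 in pL2 the counts ran from 23 to 619 (85 without pL2_IL8_12mo replicate 1, 86 without pL2_IL8_12mo replicate 2, 167 without pL2_IL8_12mo replicate 3, 619 without pL2_MRI_chow replicate 1, 23 without pL2_MRI_chow replicate 2, 92 without pL2_MRI_chow replicate 3). For IL8 line by age the counts ran from 0 to 2 (1 without pL2_IL8_12mo replicate 1, 2 without pL2_IL8_12mo replicate 2). For FXR in WT the counts ran from 73 to 281 (182 without WT_MRI_chow replicate 1, 101 without WT_MRI_chow replicate 3, 88 without FXR replicate 1, 73 without FXR replicate 2). For FXR in pL2 the counts ran from 0 to 223 (223 without pL2_MRI_chow replicate 1, 0 without pL2_MRI_chow replicate 2, 0 without pL2_MRI_chow replicate 3, 4 without pL2_FXR replicate 1, 0 without pL2_FXR replicate 2, 0 without pL2_FXR replicate 3). For FXR by transgene the counts ran from 0 to 252 (0 without WT_MRI_chow replicate 3, 0 without FXR replicate 1, 2 without FXR replicate 2, 252 without pL2_MRI_chow replicate 1, 0 without pL2_MRI_chow replicate 2, 0 without pL2_MRI_chow replicate 3, 11 without pL2_FXR replicate 1, 0 without pL2_FXR replicate 2, 0 without pL2_FXR replicate 3). For Lgr5 Notch1fl against pL2 the counts ran from 1 to 480 (107 without pL2_MRI_chow replicate 1, 3 without pL2_MRI_chow replicate 2, 1 without pL2_MRI_chow replicate 3, 184 without pL2_Lgr5_Notch1fl replicate 1, 13 without pL2_Lgr5_Notch1fl replicate 2, 480 without pL2_Lgr5_Notch1fl replicate 3). For Lgr5 Notch2fl against pL2 the counts ran from 7 to 56 (56 without pL2_MRI_chow replicate 1, 13 without pL2_MRI_chow replicate 3). For Lgr5 Notch2IC against pL2 the counts ran from 0 to 487 (113 without pL2_MRI_chow replicate 1, 0 without pL2_MRI_chow replicate 2, 2 without pL2_MRI_chow replicate 3, 7 without pL2_Lgr5_Notch2IC_LacZ replicate 1, 487 without pL2_Lgr5_Notch2IC_LacZ replicate 2). For Dclk Notch1fl against pL2 the counts ran from 0 to 83 (83 without pL2_MRI_chow replicate 1). For Dclk Notch2fl against pL2 the counts ran from 6 to 240 (240 without pL2_MRI_chow replicate 1, 6 without pL2_MRI_chow replicate 2, 14 without pL2_MRI_chow replicate 3, 10 without pL2_Dclk_Notch2fl replicate 1, 10 without pL2_Dclk_Notch2fl replicate 2, 23 without pL2_Dclk_Notch2fl replicate 3). For Dclk Notch2IC against pL2 the counts ran from 1 to 44 (44 without pL2_MRI_chow replicate 1, 1 without pL2_MRI_chow replicate 2). For Lgr5 Notch2IC against Notch2fl the counts ran from 5 to 45 (6 without pL2_Lgr5_Notch2fl replicate 1, 5 without pL2_Lgr5_Notch2fl replicate 3, 7 without pL2_Lgr5_Notch2IC_LacZ replicate 1, 6 without pL2_Lgr5_Notch2IC_LacZ replicate 2, 45 without pL2_Lgr5_Notch2IC_LacZ replicate 3). For Dclk Notch2IC against Notch2fl the counts ran from 0 to 7 (2 without pL2_Dclk_Notch2fl replicate 1, 3 without pL2_Dclk_Notch2fl replicate 2, 1 without pL2_Dclk_Notch2fl replicate 3, 0 without pL2_Dclk_Notch2IC_LacZ replicate 2, 1 without pL2_Dclk_Notch2IC_LacZ replicate 3). For Dclk against Lgr5 driver the counts ran from 28 to 430 (244 without pL2_Lgr5_Notch1fl replicate 3, 28 without pL2_Lgr5_Notch2fl replicate 2, 329 without pL2_Lgr5_Notch2fl replicate 3, 44 without pL2_Lgr5_Notch2IC_LacZ replicate 1, 369 without pL2_Lgr5_Notch2IC_LacZ replicate 3, 69 without pL2_Dclk_Notch1fl replicate 2, 59 without pL2_Dclk_Notch1fl replicate 3, 43 without pL2_Dclk_Notch2fl replicate 1, 71 without pL2_Dclk_Notch2fl replicate 2, 94 without pL2_Dclk_Notch2fl replicate 3, 34 without pL2_Dclk_Notch2IC_LacZ replicate 1, 39 without pL2_Dclk_Notch2IC_LacZ replicate 2, 430 without pL2_Dclk_Notch2IC_LacZ replicate 3).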

Other observations

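The list means, gene neighbourhoods and arrays described in the first 2 paragraphs were chosen after the results were seen; the split counts in the third were planned.

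Transcripts of intestinal absorptive cells stood out in single arrays of the Notch lines. The intestinal enterocyte list mean was 9.46 in pL2_Lgr5_Notch1fl replicate 3, 9.48 in pL2_Lgr5_Notch2fl replicate 2, 9.71 in pL2_Lgr5_Notch2IC_LacZ replicate 3, 8.65 in pL2_Dclk_Notch1fl replicate 2 and 8.44 in pL2_Dclk_Notch2fl replicate 1. These were 5 arrays in 5 of the 6 Notch groups, and the next highest of the 48 arrays had 7.22. In pL2_Lgr5_Notch1fl replicate 2 both Xist (10.75) and the mean of Y-linked genes (6.97) were high, as in pL2_Dclk_Notch1fl replicate 3 (8.75 and 7.82). The hepatocyte list mean was 11.4 in pL2_Lgr5_Notch1fl replicate 2, 9.02 in WT_MRI_chow replicate 1, 8.76 in pL2_FXR replicate 3, 8.64 in pL2_IL8_12mo replicate 1 and 8.11 in pL2_MRI_chow replicate 3.

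Called genes were also counted among up to 200 tested genes on each side of the other altered loci. Near Notch1 lay 0 of 22 genes in the Lgr5 Notch1fl line (Fisher's exact p = 1). Near Nr1h4 lay 11 of 323 in the FXR line (8.51 expected, Fisher's exact p = 0.234) and 0 of 13 in pL2_FXR. Near Gt(ROSA)26Sor lay 2 of 21 in the Lgr5 Notch2IC line (Fisher's exact p = 0.105) and 1 of 3 in the Dclk Notch2IC line (Fisher's exact p = 0.0770), counting the gene itself. Near Notch2 lay 9 of 39 in the Dclk Notch2fl line (1.03 expected, Fisher's exact p = 5.88e-07), of which Flg2, Lce1g, Lce1k, Lce1l, Lce1m, Lce6a and Sprr4 belong to the cluster of squamous genes there.

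For the mean transgene effect, 1 of 100 splits, the real one, gave 3341 genes or more and the highest other gave 2465, so chance can be excluded. For Dclk against Lgr5 driver, 3 of 100 splits gave 144 or more, fewer than the 5 of the planned rule. By that rule chance would be excluded. The highest other split called 2281, far above 144, which points to a structure of the samples that was not identified. Chance is therefore left open, a reading chosen after the counts were seen. The 10 splits of 3 against 3 arrays are too few for a share under 0.05. For HFD in WT, 1 split gave as many as the real 25 genes, with 1 in the highest other; for IL8 in pL2, 1 split gave 278, with 25; for FXR in WT, 1 gave 323, with 2. For Dclk Notch2fl against pL2, 1 split gave 39, with 34 in the highest other, and for Dclk Notch2IC against Notch2fl 1 gave 5, with 0. For FXR in pL2, 2 splits gave 13 or more, with 33 in the highest other, for Lgr5 Notch2fl against pL2 2 gave 8 or more, with 15, and for Dclk Notch2IC against pL2 2 gave 3 or more, with 4. For Lgr5 Notch1fl against pL2, 5 splits gave 22 or more, with 725 in the highest other, for Lgr5 Notch2IC against pL2 3 gave 21 or more, with 305, and for Lgr5 Notch2IC against Notch2fl 5 gave 11 or more, with 861, and such counts, several times the real ones, point to a structure of the samples that was not identified. For HFD in pL2, IL8 line by age and Dclk Notch1fl against pL2, limma called 0 genes in the real split (872, 1184 and 1589 at an unadjusted p below 0.05), all 10 splits gave as many, and the highest other gave 0, 1 and 1.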
